A study of Thermococcus kodakarensis with 4 samples.

How the data were processed

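Total RNA of wild-type KOD1 and of the TK1545 knockout was made into small RNA libraries for SOLiD sequencing, and the amplified cDNA was selected at 100 to 150 nt, per the labels' protocols. The submitters' processing notes name FastQC, cutadapt, Bowtie2 and featureCounts, without versions. The program that called circular junctions, the genome build, the handling of strand and any minimum for listing a junction were not given in the sources used here. Size selection limits which molecules were read, so a junction read comes from a short fragment across the junction and not from an intact long circle.

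Each deposited table lists junctions with their start, end and length, the authors' counts of reads aligned inside the interval and of reads over the junction, and RPKM values deposited for both. The listed minimum was 1 junction read and 36 nt. The RPKM of aligned reads fits reads per 1000000 library reads and kilobase of the interval in every line with aligned reads. This gave the library totals (20312863, 11740887, 15172100 and 12952854 reads). With these totals the junction RPKM fits the same formula, with a length of 51 nt, in every line. In wild-type replicate 2 the headers of the 2 RPKM columns are exchanged, and the values were read by what they fit. Knockout replicate 2 lists 2024590 to 2027600 on 2 lines, which were summed to 3763 reads. Junctions were matched between tables on exact start and end, and a junction that a table does not list was taken as 0.

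Junction ends within 1 to 5 nt of each other occurred in 1 pair within single libraries where the rate between libraries predicts 121, and at 6 to 10 nt in 129 pairs at 1.06 times that rate. So a count of 0 at exact ends can go with reads listed at neighbouring ends, and levels over all ends of a locus are given beside exact ones. Other ends of a locus are junctions of 36 to 90 nt that overlap by at least 50% of the longer one. Aligned reads are known only where a library lists the junction.

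Classes and gene names came from a RefSeq gene table of assembly ASM996v1, used for names and neighbours only. Of 2670 distinct junction ends, 22 equalled an end of one of 53 stable RNA genes, against a median of 3 and at most 6 at 80 shifted placements. A junction inside 16S or 23S rRNA, with 60 nt of margin, took that class, and one with at least 50% of its length in a single other stable RNA gene took the class of that gene. Of the rest, a junction was protein-coding where its overlaps with all annotated genes added up to at least 50% of its length, which can be several genes, and otherwise intergenic, and the gene with the largest overlap is named. Ends over 20000 nt apart formed a separate class. The table holds no product words and the junctions no strand, so the planned classes of C/D box, H/ACA, CRISPR and antisense RNA, and the planned protein lists, could not be filled. An intergenic junction can thus lie in an RNA that this table does not name. Of the planned lists, rRNA alone, with 7 tested members, reached the minimum of 5. A list of 20 tested intergenic and coding circles of 55 to 75 nt was drawn up after the falls were seen. It entered the adjustment of the list tests but is described by its counts alone.

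Counts were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) in a quasi-likelihood fit with genotype as its term, filterByExpr, two-sided tests and Benjamini-Hochberg adjusted p under 0.05. The filter kept 30 of 1776 junctions. TMM factors and library totals were both planned before the data were examined. DESeq2 1.42.0 and RLE factors (relative log expression) were alternatives, with other filters, merged ends, sums per locus, a replicate term and each library left out. In 50 simulations on the 30 junctions with 10 changed 16-fold, edgeR recovered 93.0% with TMM and 92.2% with library totals. With 18 lowered 128-fold it recovered 92.4% and 96.7%, and called 23.8% of unchanged junctions higher with TMM against 0.833% with library totals. Values per library were compared with exact permutation tests (scipy 1.17.1, numpy 2.4.6), shares have 95% Clopper-Pearson intervals, and figures used matplotlib 3.10.9. Folds of single junctions are of pooled reads per library total.

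Replicates were compared before averaging. Chi-square tests of counts over junctions differed from sampling noise within the wild type (chi-square 1999.74, 41 degrees of freedom) and within the knockout (chi-square 234.387, 20 degrees of freedom), so no library was counted as a copy of another. Reads aligned to the chromosome made up 50.5%, 62.2%, 42.8% and 47.1% of the library totals.

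Junctions named were the 10 with the largest rise and the 10 with the largest fall among those past the test with TMM whose knockout values both lay on one side of both wild-type values, filled by the smallest p where fewer passed, the 5 most abundant, and those of TK1545, rtcB, rRNA, signal recognition particle RNA, RNase P RNA and the tRNAs for tryptophan and methionine. In the direction of rise 3 passed and 6 filled the list. The gene table does not say which amino acid a tRNA gene serves, so the tested tRNA-gene junctions were named instead. The junctions 963853 to 963919 and 2024591 to 2027533 were named after their values were seen.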

Results

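Circular RNA junctions were compared between the wild-type strain KOD1 of Thermococcus kodakarensis, a hyperthermophilic archaeon, and a strain in which TK1545, the gene of an ATP-dependent RNA ligase, had been knocked out. An RNA ligase joins RNA ends, and the comparison asks which circular RNAs differ between the strains. Each strain had 2 small RNA libraries, and the labels do not say whether these came from separate cultures, so p-values measure the spread between libraries, which may be technical. A circular junction is read when the 3′ end of an RNA segment is found joined to its own 5′ end. Library totals were 20312863 and 11740887 reads for wild-type replicates 1 and 2 and 15172100 and 12952854 for knockout replicates 1 and 2, and levels are given as RPM, reads per 1000000 of these library reads. The wild-type libraries listed 645 and 496 junctions with 42863 and 31295 junction reads. The knockout libraries listed 383 and 396 junctions with 6897 and 8995 junction reads. A count of 0 allows up to 0.148, 0.256, 0.198 and 0.232 RPM in these libraries, in the same order, and intervals and floors cover counting error only. Positions are on the chromosome as numbered in the deposited tables, for which no genome build is named, and strand is not given.

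No junction was listed at TK1545 in any of the 4 libraries, so the deletion could not be checked from these values. The same held for rtcB (TK0358), the gene of the other archaeal RNA ligase family, and for RNase P RNA. Both knockout libraries stood apart from both wild-type libraries in the level of intergenic junctions, as described next.

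Circles from intergenic positions fell in the knockout, and this was the largest difference between the strains among the classes tested. Their junctions held 1345 ± 12.3 RPM in the wild type and 8.60 ± 0.147 in the knockout (SD, n = 2 each), a 156-fold difference. Junctions within the 16S rRNA, at 14.4 ± 2.27 and 6.65 ± 0.743 RPM, and within protein-coding genes, at 15.5 ± 2.45 and 6.93 ± 1.23, passed the test as lower only with their most abundant junction included. Junctions of the 23S rRNA, at 965 ± 388 and 503 ± 165 RPM, and of tRNA genes, at 30.7 ± 10.9 and 37.5 ± 0.915, did not pass the test. With edgeR's quasi-likelihood test on class sums scaled to library totals and adjusted over 8 classes, the intergenic log2 change was −7.29 (SE 0.0752, adjusted p = 8.84e-06), that of the 16S rRNA −1.11 (adjusted p = 0.0319) and that of protein-coding genes −1.16 (adjusted p = 0.0319). The change was −0.94 for the 23S rRNA (adjusted p = 0.128) and 0.29 for tRNA genes (adjusted p = 0.408). Signal recognition particle RNA, part of the protein-targeting machinery, had 13 and 4 junction reads in the wild type and 2 and 2 in the knockout (adjusted p = 0.0633), and 5S rRNA had 2, 0, 1 and 0. Junctions that spanned the region between 16S and 23S rRNA held 11.3 and 7.73 RPM (adjusted p = 0.128). Without its most abundant junction, the intergenic class still held 341 ± 47.1 RPM in the wild type and 6.12 ± 0.0795 in the knockout, a 55.7-fold difference (log2 change −5.80, adjusted p = 4.63e-08). Nearly all of the class contrast came from 18 circles described below, 17 of them intergenic. Over all ends their loci held 1337 RPM in the wild type and 4.94 in the knockout. The intergenic class without these circles was not tested. The same removal, chosen after the data were seen, left the 16S rRNA at 6.45 ± 0.761 and 4.16 ± 0.564 RPM (log2 change −0.63, adjusted p = 0.0798) and protein-coding genes at 10.3 ± 1.73 and 6.93 ± 1.23 RPM (log2 change −0.56, adjusted p = 0.128). Both of these calls also ended without wild-type replicate 2 (adjusted p = 0.0536), without knockout replicate 1 (adjusted p = 0.191) and without knockout replicate 2 (adjusted p = 0.131). Without the circle in TK_RS12055 described later, the junctions of tRNA genes held 3.99 ± 0.344 and 1.51 ± 0.370 RPM (log2 change −1.42, adjusted p = 0.0202).

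**Figure D1:**
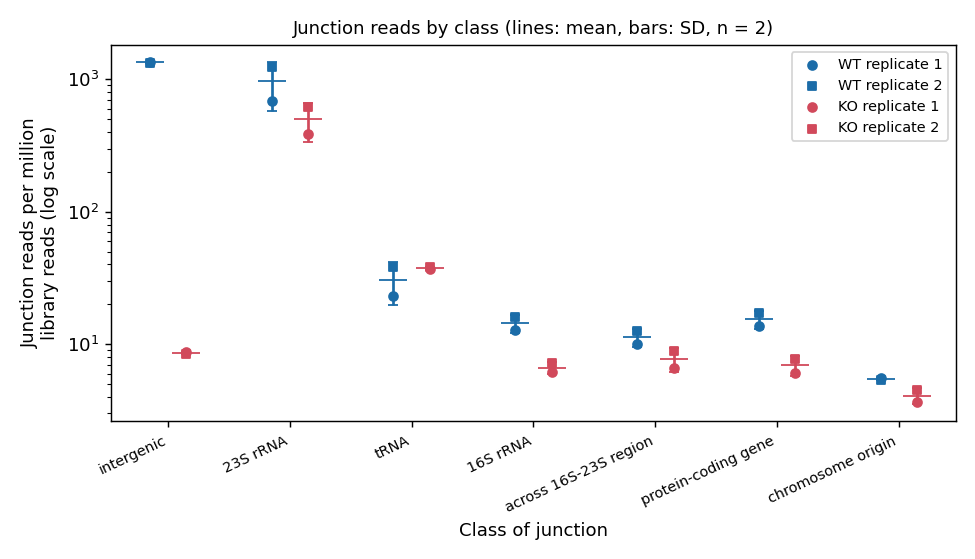
Junction reads in RPM (log scale) by class of junction, with points for the 2 wild-type (blue) and 2 knockout (red) libraries, lines for the means and bars for the SD. The intergenic class lies at 1345 RPM in the wild type and 8.60 in the knockout, while the tRNA class lies at 30.7 and 37.5.

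The makeup of the junction reads differed as well. Shares of a library add up to the whole, so the fall of intergenic reads by itself raises the shares of the other classes. The 23S rRNA, 16S rRNA and protein-coding classes had lower mean RPM in the knockout, although their shares were higher. Intergenic junctions took 64.1% (95% Clopper-Pearson interval 63.7 to 64.6) and 50.1% (49.6 to 50.7) of junction reads in the wild-type libraries, against 1.91% (1.60 to 2.27) and 1.22% (1.01 to 1.47) in the knockout libraries. The 23S rRNA took 32.7% and 46.5% in the wild type and 84.9% and 89.2% in the knockout, and tRNA genes took 1.09% and 1.44% against 8.10% and 5.49%. The share of the 16S rRNA was 0.607% and 0.601% against 1.35% and 1.03%, and that of protein-coding genes 0.651% and 0.645% against 1.33% and 1.12%. In each of these 5 classes both knockout libraries lay on one side of both wild-type libraries, and the exact two-sided permutation test gave p = 0.333, the smallest value that 2 libraries against 2 allow. Summed over all classes, junction reads stood at 2388 ± 393 RPM in the wild type and 575 ± 170 in the knockout (exact permutation p = 0.333), a 4.16-fold difference. Without intergenic and coding junctions of 55 to 75 nt, a length range chosen after the values were seen, the sums were 1039 ± 404 and 566 ± 170.

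Among single junctions, 18 circles of 61 to 71 nt fell in the knockout with both scalings used, 17 of them intergenic and 1 in the coding gene TK1648. The most abundant, at 51410 to 51476 and overlapping the edge of TK0058 by 4 nt, went from 21240 and 11291 reads in the wild type to 40 and 30 in the knockout. That is 1004 ± 59.4 against 2.48 ± 0.227 RPM, 408-fold lower (95% counting interval 323 to 523). Of the 18 circles, 9 had no read in either knockout library at the wild-type ends, and at 7 of these 9 the knockout libraries held reads at slightly different ends. With all ends at a locus summed, the knockout lay 5.56-fold to 781-fold lower at the 16 loci with any knockout read, with a median of 149.5-fold.

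The test covered the 30 junctions with enough reads, which held 96.8% of all junction reads. With TMM factors (trimmed mean of M values, computed on the junction counts) edgeR called 18 junctions lower and 3 higher in the knockout. Scaled to library totals it called 20 lower and 1 higher, and 18 were lower in both. The shift between the scalings was −1.04 in the median log2 change, so a log2 change near 0 with TMM lay near −1.04 per library read. The test with TMM depended on both wild-type libraries: without either replicate 1 or replicate 2 of the wild type it called 0 lower and 0 higher (6 and 8 of 28 and 30 tested junctions at an unadjusted p under 0.05), while scaling to library totals called 12 and 13 lower and 0 higher.

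The circle at 558818 to 558879, which overlaps the edge of TK0656 by 9 nt, had 1060 and 721 reads in the wild type and none at these ends in the knockout (adjusted p = 0.000169 with TMM and 0.000769 with library totals). With 2 knockout reads at other ends of that locus, the fall was 781-fold (counting interval 216 to 6457). At 2070053 to 2070114, 819 and 656 reads stood against 1 and 2. At 1226948 to 1227017, touching the edge of tmk (TK1403), the thymidylate kinase gene, 871 and 566 reads stood against 2 and 0. The circle at 1894519 to 1894579, at the edge of TK2109, had 342 and 385 wild-type reads and 1 knockout read at other ends. At 1167276 to 1167338 there were 324 and 178 reads in the wild type and none at any ends in the knockout, which puts it at least 147-fold lower against a floor of 3 reads over both knockout libraries. The coding-gene circle at 1446206 to 1446266 had 95 and 67 reads against 2 in the knockout, all at other ends, 71.1-fold lower (counting interval 19.4 to 592). That at 1593064 to 1593134 had 64 and 23 reads against 3 at other ends, 25.4-fold lower (8.42 to 126). These 7 circles passed the test with both scalings, at adjusted p between 0.000169 and 0.00675. With library totals the call at 1446206 to 1446266 ended without wild-type replicate 1 (adjusted p = 0.0545) and that at 1593064 to 1593134 without wild-type replicate 2 (adjusted p = 0.116).

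At 3 of the 10 junctions with the largest falls, the knockout libraries together held 10 or more reads, all of them at ends a few nucleotides away. At 316130 to 316191 the wild type had 864 and 504 reads, and the knockout had 7 and 3 reads at 316128 to 316189, a circle of the same 62 nt. At 1476847 to 1476912 the wild type had 272 and 243 reads, and the knockout had 6 and 10 at 1476851 to 1476912. At 940145 to 940207 the wild type had 43 and 32 reads, and the knockout had 6 and 6 at 940145 to 940205. Counted over all ends, the falls were 120.0-fold, 28.3-fold and 5.56-fold. For the last of these the edgeR call with TMM ended when ends within 5 nt were merged (log2 change −1.29, adjusted p = 0.0749) or within 2 nt (log2 change −0.97, adjusted p = 0.314), while with library totals all 18 calls held under both.

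**Figure D2:**
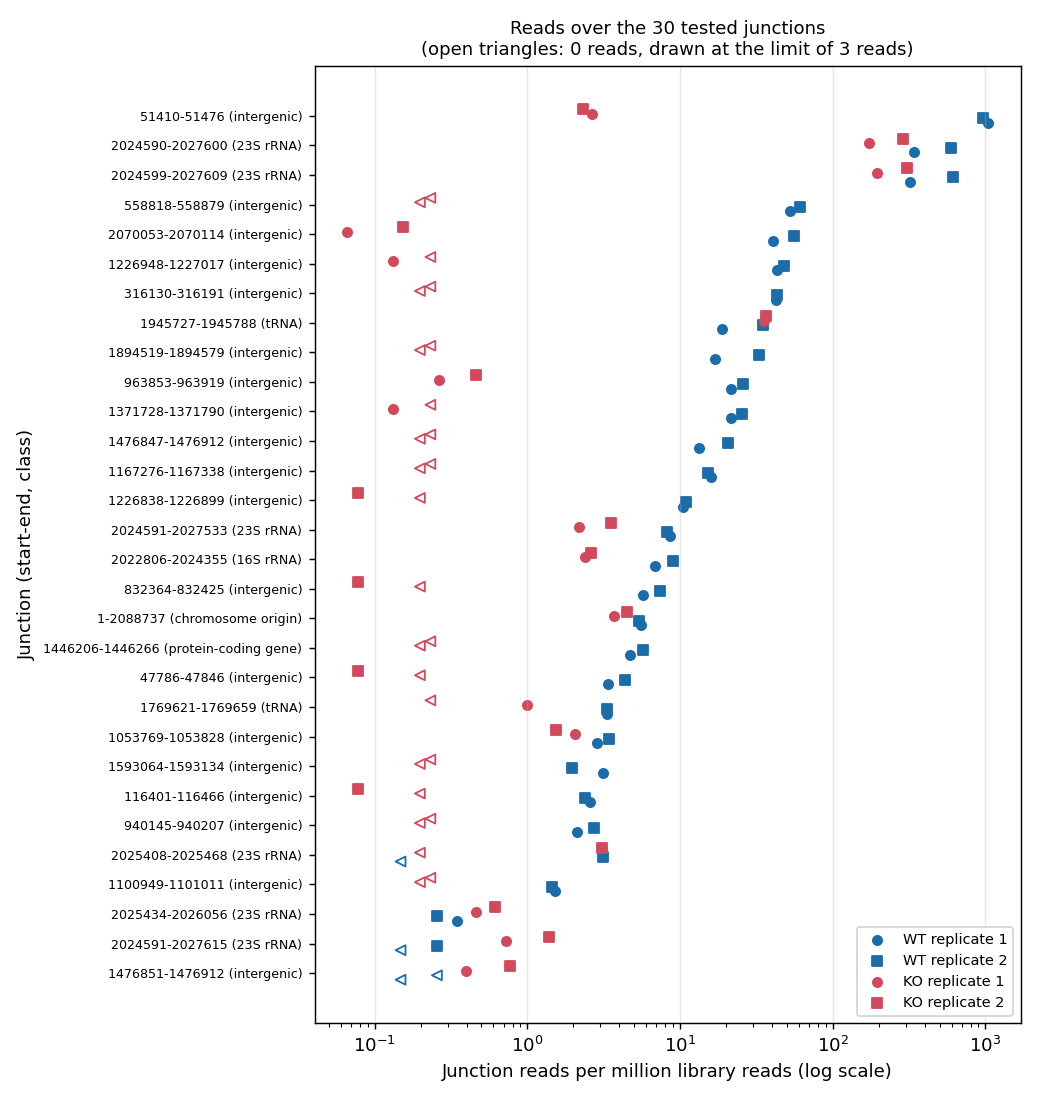
RPM (log scale) over each of the 30 tested junctions in the 2 wild-type (blue) and 2 knockout (red) libraries, with open triangles for 0 reads drawn at the limit of 3 reads. The circle at 51410 to 51476 lies at 1004 RPM in the wild type and 2.48 in the knockout, and 9 of the 18 circles that fell have 0 reads at these ends in both knockout libraries.

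A small circle inside a tRNA gene was abundant in both strains. TK_RS12055, at 140 nt the longest of the 47 annotated tRNA genes, holds a 62 nt circle at 1945727 to 1945788 with 382 and 407 reads in the wild type and 540 and 471 in the knockout, or 26.7 ± 11.2 and 36 ± 0.545 RPM. It passed the test as higher with TMM (log2 change 1.60, adjusted p = 0.00807) but not with library totals (log2 change 0.43, SE 0.35, adjusted p = 0.298). The call with TMM ended without a filter (log2 change 1.26, adjusted p = 0.0658) and without wild-type replicate 1 (adjusted p = 0.186) or 2 (adjusted p = 0.17). A 60 nt intergenic circle at 1053769 to 1053828, with 58 and 40 reads in the wild type and 31 and 20 in the knockout, passed with neither at these ends, and its log2 change was 0.32 with TMM and −0.80 with library totals. With library totals it passed as lower with ends within 5 nt merged (log2 change −0.78, adjusted p = 0.0433) and without knockout replicate 1 (log2 change −1.01, adjusted p = 0.0482). A 39 nt circle in the tRNA gene TKt36 had 67 and 39 reads at 1769621 to 1769659 in the wild type and 15 in knockout replicate 1, and the 15 reads of knockout replicate 2 lay 1 nt away. At the exact ends it passed with neither scaling (adjusted p = 0.256 and 0.147), and with ends within 5 nt merged its log2 change was −1.62 with library totals (adjusted p = 0.000129) and −0.48 with TMM (adjusted p = 0.43). At the exact ends it passed as lower without knockout replicate 1 with TMM (log2 change −8.35, adjusted p = 0.00375) and library totals (log2 change −8.64, adjusted p = 0.00425), and without knockout replicate 2 with library totals (log2 change −1.74, adjusted p = 0.00747).

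The only junction called higher with both scalings was 1476851 to 1476912 (0, 0, 6 and 10 reads), the alternative end of a locus whose summed reads fell. Both wild-type libraries listed that locus at 1476847 to 1476912 (272 and 243 reads). Junctions 1 to 5 nt apart were almost never listed together in a library (1 pair where 121 are predicted). The wild-type counts of 0 may thus come from the listing, so no fold is given and this call cannot show a rise. This call ended without a filter (adjusted p = 0.626 with TMM and 0.585 with library totals), with a minimum of 10 summed reads under library totals (adjusted p = 0.102), and without either wild-type library with both scalings. The junction 2024591 to 2027615 in the 23S rRNA gene TKr06 had 0 and 3 reads in the wild type and 11 and 18 in the knockout (11-fold higher), with adjusted p = 0.0234 with TMM and 0.102 with library totals. The call with TMM ended without a filter (adjusted p = 0.626), with a minimum of 10 summed reads (adjusted p = 0.126) and without knockout replicate 1 (adjusted p = 0.121). It also ended without wild-type replicate 1 or 2, where the log2 change moved from 4.38 to 3.27 and 7.28 with TMM, and from 3.22 to 2.01 and 7.10 with library totals. With ends within 2 nt merged it passed as higher with library totals too (adjusted p = 0.0395). Also in the 23S rRNA, 2025434 to 2026056 (7 and 3 against 7 and 8 reads) did not pass with either scaling (adjusted p = 0.0621 and 0.204). It passed as higher with DESeq2 (adjusted p = 0.0199), with table totals and no TMM factors (adjusted p = 0.00248), and with TMM when ends within 2 nt (adjusted p = 0.032) or 5 nt (adjusted p = 0.0438) were merged. At its exact ends 2025408 to 2025468, where reads were listed in wild-type replicate 2 (37) and knockout replicate 2 (40) alone, did not pass with either scaling. With ends within 2 or 5 nt merged it passed as higher with TMM (log2 change 1.89 and 1.39, adjusted p = 0.0418 and adjusted p = 0.0174) but not with library totals (log2 change 0.02 and 0.19).

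Circles the length of the whole 23S rRNA were abundant in both strains, and their direction turned with the scaling. The junctions 2024599 to 2027609 and 2024590 to 2027600, both 3011 nt long, held 467 ± 204 and 469 ± 179 RPM in the wild type and 249 ± 77.9 and 232 ± 83.4 in the knockout. Their log2 changes were 0.30 and 0.19 with TMM (adjusted p = 0.604 and 0.726) and −0.91 and −1.02 with library totals (adjusted p = 0.142 and 0.112). With ends within 5 nt merged both passed as lower with library totals (adjusted p = 0.0384 and 0.0219), and with the totals of the junction tables and no TMM factors both passed as higher (log2 change 1.25 and 1.12, adjusted p = 0.0212 and 0.0228). Those totals, over tested junctions, were 41802 and 30536 reads in the wild type and 6348 and 8452 in the knockout. Totals that fall this far place log2 changes above those with library totals, so these calls do not show a rise per library read. The shorter 23S rRNA junction at 2024591 to 2027533 (175 and 96 against 33 and 46 reads) and the 16S rRNA junction at 2022806 to 2024355 (140 and 106 against 36 and 34) fell with library totals (log2 change −1.55 and −1.67, adjusted p = 0.0200 and 0.0103) but did not pass with TMM (−0.38 and −0.51). Both calls ended without a filter (adjusted p = 0.57 and adjusted p = 0.45), without wild-type replicate 1 (adjusted p = 0.41 and adjusted p = 0.284) and without wild-type replicate 2 (adjusted p = 0.391 and adjusted p = 0.413). With TMM both passed as lower without knockout replicate 2 (adjusted p = 0.0278 and adjusted p = 0.0481). A read across the coordinate start of the circular chromosome, which reports no RNA circle, had 113, 63, 56 and 58 reads (log2 change 0.73 with TMM, −0.42 with library totals). It passed as higher with TMM without knockout replicate 1 (log2 change 1.03, adjusted p = 0.0313) and with table totals and no TMM factors (log2 change 1.71, adjusted p = 0.00662).

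As a list fixed in advance, the 7 tested rRNA junctions stood above the other junctions in camera, edgeR's competitive test, in a table where most other junctions fell. Such falls by themselves place a list outside them above the rest, so this rank shows no rise. Camera gave adjusted p = 0.00228 with TMM and adjusted p = 0.00400 with library totals. The adjustment was over 2 lists, the other being the 20 circles drawn up later. With an estimated correlation camera gave adjusted p = 0.252 and adjusted p = 0.238. Of the 7, edgeR called 0 lower and 1 higher with TMM and 2 lower and 0 higher with library totals. Adjusted over the list alone it called 0 and 0 with TMM, and 2 lower with library totals. The median log2 change was 0.30 with TMM and −0.91 with library totals, so with library totals the median and camera differed in sign, and fry, which tests the list against no change, gave the direction down with adjusted p = 0.259.

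Reads aligned inside most of the intervals of the circles that fell remained in the knockout. The tables also give reads aligned inside each listed interval, a value set beside the junction reads after the data were seen. For the 9 of the 18 circles listed in both strains, the median knockout to wild-type ratio of aligned reads was 0.843 (range 0.50 to 1.91, 7 lower and 2 higher), against a median of 0.00333 for junction reads. The knockout value came from both libraries for 3 of these 9 circles and from 1 library for 6. For the 7 circles that the knockout listed at other ends only, the ratio of aligned reads in these neighbouring intervals had a median of 1.36, with 0.0983 at 316130 to 316191 and 0.930 to 1.91 at the other loci. These ratios set the knockout interval against the wild-type interval, which has slightly different ends, so they do not compare the same stretch. At 51410 to 51476, aligned reads stood at 254 ± 28.0 and 127 ± 3.85 RPM. At 963853 to 963919 they stood at 1105 and 2114 RPM, while junction reads there went from 435 and 301 to 4 and 6. In the tRNA-gene circle there were 2.85 and 3.71 junction reads per 100 aligned in the wild type and 3.17 and 3.20 in the knockout.

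**Figure D3:**
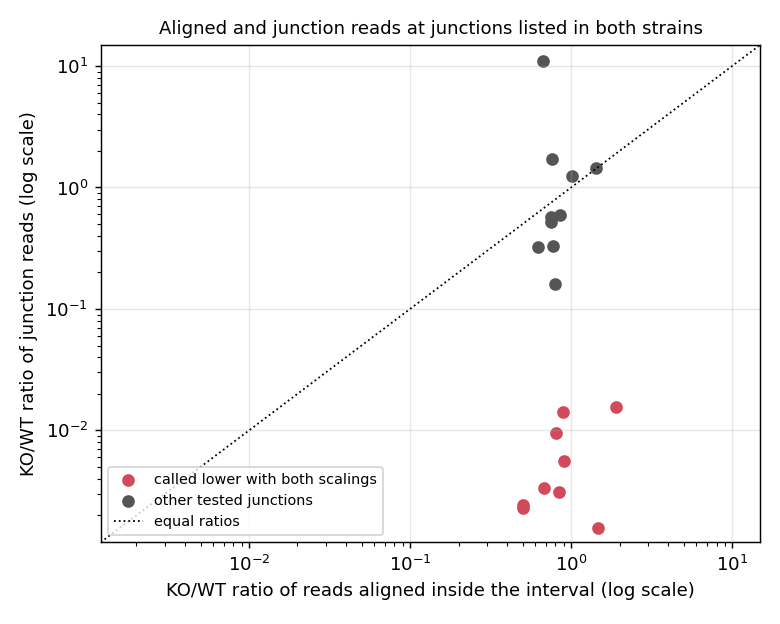
Knockout to wild-type ratio of reads aligned inside an interval (horizontal, log scale) against the same ratio of junction reads (vertical, log scale) for tested junctions listed in both strains. The 9 circles called lower with both scalings (red), 6 of them with a knockout value for aligned reads from 1 library, have aligned ratios from 0.50 to 1.91 and junction ratios of at most 0.0155, far under the dotted line of equal ratios.

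The median circle, weighted by reads, was 67 nt long in both wild-type libraries and 3011 nt in both knockout libraries (exact permutation p = 0.333, the smallest possible). The single junction 51410 to 51476, with 49.6% and 36.1% of the wild-type junction reads, carried this contrast, and without it the median was 3011 nt in all 4 libraries. Counted per junction, the medians of 412.5 and 434 nt in the wild type and 554 and 424 nt in the knockout did not separate the strains (exact permutation p = 0.667). Most junctions were rare: 1676 of the 1776 distinct junctions (94.4%) were listed in 1 library, and 12 were listed in all 4. The wild-type replicates shared 5.26% of their junctions and the knockout replicates 4.01%, which rose to 71.8% and 52.9% for junctions with at least 10 reads.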

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

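The scaling to chromosome-aligned reads or to junction reads over the coordinate origin, the merging of junctions of equal length shifted by up to 10 nt, the removal of each class's most abundant junction from its edgeR class sum and of 51410 to 51476 from the circle size, and the alternatives for called junctions outside the naming rule, were chosen after the data were seen. With library totals all 18 circles stayed lower and past the test under the block, both added scalings, every merging of ends, without either knockout library and with at least 10 reads summed, and 16 stayed without a filter. With TMM all 18 stayed under RLE, table totals without factors, DESeq2, equal-length merging and without either knockout library, 17 with ends within 2 or 5 nt merged or under the block, and 16 without a filter or with at least 10 reads. Leaving out each library gave 0 to 21 lower and 0 to 3 higher with TMM, and 12 to 24 lower and 0 to 1 higher with library totals; the lowest counts came without wild-type replicate 1 or 2, with 14 and 16 of the 18 testable and all of these still negative, and a lone library is assumed to vary like the other group. Junctions called higher numbered 7 without TMM factors, 5 and 6 with ends within 2 and 5 nt merged and 7 per locus in place of 3. With library totals they numbered 0 without a filter, with at least 10 reads or per locus, and 2 with ends within 2 or 5 nt or equal lengths merged, in place of 1. The simulations with 18 lowered junctions gave false rises with TMM (23.8% of unchanged junctions). Why the counts moved between the other settings was not tested.

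The experiment numbers are not stated to mark a shared batch, and replicate differences over 30 junctions correlated with r = 0.72 (Spearman 0.29) in only 2 pairs, so the libraries were not treated as paired. With the replicate block the 3011 nt 23S rRNA pair was called lower with library totals (log2 change −0.87 and −1.01, adjusted p = 1.22e-09 and 5.7e-11) but not with TMM. Without the block, log2 changes of −0.91 and −1.02 did not pass (adjusted p = 0.142 and 0.112). The block leaves few residual degrees of freedom, so such small p-values are no strong evidence of a fall. Under the block 2022806 to 2024355 (adjusted p = 0.0603) and 2024591 to 2027533 (adjusted p = 0.063) no longer passed with library totals, where 1769621 to 1769659 passed as lower (log2 change −2.91, adjusted p = 0.0263), and 1476851 to 1476912 (adjusted p = 0.0537) and 1100949 to 1101011 (adjusted p = 0.0591) no longer passed with TMM. With it edgeR called 17 lower and 2 higher with TMM and 21 and 1 with library totals, and the rRNA list had adjusted p = 0.00107 and adjusted p = 0.0295 in camera. In fry that list went down with library totals under the block (adjusted p = 0.0239), which passes where the fit without it did not (adjusted p = 0.259). In camera that list lost its call with an estimated correlation, both without the block (adjusted p = 0.252 and adjusted p = 0.238) and with it (adjusted p = 0.276 and adjusted p = 0.280).

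Among 724 alternatives for the junctions of the naming rule and the others called with either scaling, 608 kept direction and call, 68 lost the call, 30 gained it and 18 turned. The turned log2 changes were all of junctions not past the test with that scaling. Leaving out each library gave −0.06 to 0.53 for 1053769 to 1053828, −0.29 to 0.73 for 2024599 to 2027609 and −0.47 to 0.65 for 2024590 to 2027600 with TMM (−0.04 and −0.09 for the last without wild-type replicate 1 or 2), and for 2025408 to 2025468 −7.28 to 7.56 with TMM and −7.61 to 7.64 with library totals (−1.03 without wild-type replicate 1). Without a filter the 23S rRNA pair had −0.17 and −0.30 with TMM, and without TMM factors 2022806 to 2024355 had 0.50. With TMM 2024591 to 2027533 had 0.54 without the factors, 0.04 with ends within 2 nt merged, and −1.11 to 0.07 leaving out each library (0.07 without knockout replicate 1). With library totals 2025408 to 2025468 had −0.03 under the block and −0.02 with no filter, at least 10 reads or equal-length merging. At 2025408 to 2025468 exact matching left 0 reads in both replicates numbered 1. These listed 29 (wild type) and 32 (knockout) reads at 2025413 to 2025466 and 2025412 to 2025469. Leaving out a replicate numbered 2 thus removed all exact-end reads of its strain, which gives the wide range there. The cause of the other turns was not tested.

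Differences of shares (knockout minus wild type, percentage points) moved with the junctions counted. Shares add up to the whole, so taking out an abundant junction or class changes every other share by arithmetic. Whether anything else moved them was not tested. Without the top junction, 51410 to 51476, they were 18.6 for 23S rRNA, 0.126 for 16S rRNA, 0.0841 for protein-coding genes and −24.3 for intergenic junctions; without rRNA 63.1 for tRNA, 10.9 for coding and −81.3 for intergenic; and with at least 5 reads 0.113 for 16S rRNA and −0.125, a reversal, for coding genes. The log2 changes of class sums without the top junction of the class were −0.63 for 16S rRNA and −0.56 for coding genes, no longer past the test, and −1.42 for tRNA, turned; leaving out each library gave −1.27 to −0.95, −1.35 to −0.98 and −0.04 to 0.70. Shared junctions of the wild-type replicates were 14.4%, 47.7% and 71.8% at 2, 5 and 10 reads, 11.3% thinned, and 8.05% and 11.6% with ends within 2 and 5 nt; of the knockout replicates 10.1%, 35.3% and 52.9%, and 6.71% and 9.65%. The size difference was 65.8 nt per junction, and 0 nt without 51410 to 51476, since the wild-type median lay on that junction. Pseudocounts and filters for normalized values did not apply to counts.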

Other observations

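The tests of linear abundance by aligned reads, of other circles of similar length, of sampling and of reporting of ends, and of the paired 23S rRNA junctions were chosen after the result was seen; the tests of scaling, of merged ends, of the background of other ends and of aligned reads at circles with other ends came before theirs. Beyond the comparisons above, the circles that fell lay mostly between genes or at their edges: 9 of the 18 touched no annotated gene, 8 overlapped a gene edge by 3 to 15 nt, and the remaining one overlapped TK1648 by 35 nt. The list of 20 circles of 55 to 75 nt was drawn around the 18 that fell, so its count of 18 lower and 1 higher junctions with both scalings describes it and tests nothing. Its other member, at 1053769 to 1053828, did not pass at its exact ends over all 4 libraries.

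The fall of 18 small circles in the knockout was set against 4 technical or indirect readings. Scaled to reads over the coordinate origin, 18 of the 18 calls held. Origin reads differed only 1.34-fold between the strains, so this scaling could hardly have ended falls of such size. It shows only that a scaling difference of that size does not account for them. With ends within 5 nt merged 18 held with library totals, which argues against exact matching as the whole of it. Reads aligned inside the intervals mostly did not fall like the junction reads. Their median knockout to wild-type ratio was 0.843 at the 9 circles listed in both strains (lowest 0.50, with 1 knockout library behind 6 of them). It was 1.36 at the 7 listed in the knockout at other ends (0.0983 at 316130 to 316191, the exception, up to 1.91), where the intervals compared differ slightly between the strains. Strand is not given, so these reads need not come from the RNAs that form the circles. At 51410 to 51476 the wild type had 446.5 and 351.2 junction reads per 100 aligned, and aligned reads there fell to a ratio of 0.50. Lower abundance of the same RNAs therefore stays open, as it does for the 2 circles with no interval listed in the knockout. A loss of every circle of this length is argued against by the other tested circles of similar length outside rRNA, 1053769 to 1053828 and 1945727 to 1945788, whose lowest ratio was 0.593. These 2 are what remained once the circles that fell were set aside, so they do not argue against a loss of most. A further 62 nt circle, 1167368 to 1167429, fell with equal-length ends merged. It had 26 and 20 wild-type reads against 1 and 1 in the knockout (edgeR adjusted p = 0.0117 with TMM and 0.000131 with library totals). That closure of the 18 circles depends on TK1545, the difference that the design names, stays a hypothesis found and tested on the same libraries. Libraries of a knockout with TK1545 put back would show, by whether these junctions return, if their level depends on TK1545. They would not by themselves separate closure from the level of the RNAs.

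At the 18 loci, 26 of 75 knockout junction reads (34.7%, interval 24 to 46.5) and 22 of 64 (34.4%, 22.9 to 47.3) had other ends than the wild-type circle, against 2 of 27350 and 2 of 15578 in the wild type. In RPM, other ends were 12.7-fold more frequent in the knockout, and the lowest interval bound of their share was 22.9%. These values would speak against sampling of the wild-type ends and against an equal background, but the listing of junctions voids both tests: pairs of junctions 1 to 5 nt apart were 0.00825 times as frequent within libraries as between them, so reads at ends near an abundant wild-type circle may be absent from its table. The bound set before for an equal background was therefore wrong, since it took listed reads for all reads. Whether knockout circles truly close at more varied ends cannot be told apart from this reporting.

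The paired 23S rRNA junctions, 2024590 to 2027600 and 2024599 to 2027609, have the same length of 3011 nt and are shifted by 9 nt. Their read ratio was 1.06, 0.975, 0.889 and 0.955 over the 4 libraries, a 1.19-fold spread (chi-square p = 1.07e-07 on reads). A repeat of that length at both ends could let a single circle be placed at either position, and 2 real circles in a near-fixed ratio would look alike in these values, so the readings cannot be told apart without the sequence. No biological explanation was tested for this pair.

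Short junctions inside 23S rRNA between 2025374 and 2025491 had 46 and 45 reads in the wild type and 52 and 57 in the knockout, led by 2025413 to 2025466 in wild-type replicate 1, 2025412 to 2025469 in knockout replicate 1 and 2025408 to 2025468 in both replicates numbered 2. All 10 junctions with ends over 20000 nt apart had 1 read each and both ends at stable RNA genes.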
